A study of Drosophila melanogaster with 2 samples.

How the data were processed

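The series holds chromatin immunoprecipitation with sequencing (ChIP-seq) on whole Drosophila melanogaster pupae that carry a transgene for a fusion of the zinc finger transcription factor Rotund (rn) with enhanced GFP, precipitated with an antibody against GFP. The labels give 2 biological replicates of this 1 group, name sonication for fragmentation, and give neither the pupal stage nor the sex. Replicate numbers were taken from the labels. With a single group no comparison between conditions was possible, and control libraries were not analysed here.

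The deposited lists are narrowPeak tables on the dm6 assembly, per the labels. For each replicate there was a ranked list and a thresholded list, and for both replicates together a pair of ranked lists, a thresholded set and a conservative thresholded set. The score of a peak in the deposited files is its irreproducible discovery rate (IDR, an estimate of the chance that a peak fails to recur between paired calls) rescaled by the authors to at most 1000. The −log10 of the IDR stands beside it in the deposited ranked lists. The lowest score in each thresholded list was 830, which corresponds to an IDR of 0.01. The signal value is the peak height as the authors' caller gave it and is not scaled between lists, so signal was used to describe and rank peaks within a list. The aligner and peak caller are not given in the sources used here. The files hold peaks and no reads, so the read depth of each library is unknown, and confidence intervals on shares cover counting error over peaks only. Intervals on percentiles cover only the draw of random genes.

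Peaks were placed on the Release 6 genome sequence and on the gene models of Ensembl release 115 (BDGP 6.54). No peak ended beyond its reference arm, and 13933 genes were compared between the Ensembl and RefSeq annotations, of which 99.99% had the same start and end. The 6 arms X, 2L, 2R, 3L, 3R and 4 held 3774 of the 3777 thresholded peaks, and the other 3 were left out. Coordinates are 1-based. A summit within 500 bp of an annotated transcript start was called a promoter summit, and the others were classed in the order coding exon, other exon, intron and intergenic. A protein-coding gene was given a peak when a summit lay in its body or up to 1000 bp upstream, so that nested or adjoining genes can share a peak.

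Observed shares at annotation classes and the overlap of replicates were set against 1000 circular shifts of the peaks along each arm. These shift tests were two-sided for classes and one-sided for overlap. Replicate peaks sharing at least 1 bp were called shared. Differences in median signal and correlations were tested with 100000 permutations, across peaks, which are not independent replicates. Gene lists were compared with 100000 random lists of the same size drawn from the 13945 protein-coding genes and matched on gene length in 20 bins, two-sided, with Benjamini-Hochberg adjustment over 22 lists. Random lists do not keep the spacing of genes, so neighbouring genes of a list counted as independent, which can make its p too small. The presence of 17 fixed motifs and of all 2080 6-mers (a 6-mer and its reverse complement counted together) in the 101 bp around a summit was compared with that in a window of equal width 500 bp away on a random side, with an exact McNemar test and Benjamini-Hochberg adjustment. Peak density of X against the autosomes was compared with an exact binomial test on arm lengths. The mean signal of all ranked peaks within 20 kb of rn was placed among 1000 random protein-coding genes, of which 988 had ranked peaks there, and so was that of w and y, common marker genes of fly transgenes. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

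The rule for genes named in the text took rn, its relative sqz, bab1, bab2, w and y in every case, the gene with the nearest start for each of the 10 strongest peaks, up to 4 genes with the strongest peak for a list past an adjusted p of 0.05 and up to 2 for other lists. Other genes were named after their values were seen. Gene lists, motifs, tests and most alternatives were chosen before the data were examined. The alternatives were the conservative set, each replicate's own set in place of the set over both, other promoter widths, other ways of giving peaks to genes, a test without length matching, other motif windows, a stricter overlap and a stricter IDR. The planned IDR of 0.01 equals the deposited threshold and removed no peak on the arms, so an IDR of 0.001 was added. The ranked list at the threshold score, the 6-mer test with base composition held and a list permutation without length matching were also added after the data were examined. Some list members were not analysed here, at most 3 in any list. The name pattern for odorant receptors also took Orcokinin, which encodes a neuropeptide precursor.

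The tests were tested on simulated data. With the observed peaks kept, lists of genes drawn at random from the 13945 were tested, and 2.5% of them had a p under 0.05. Of such lists whose members were given a peak in 4 of 10 cases, 95% did. Members were drawn without regard to position or length, so these rates do not cover lists of neighbouring or mostly long genes. With 3774 random summits the promoter shift test had a p under 0.05 in 6.5% of runs, and in 100% of runs when 1 in 20 summits was moved to a start. No 6-mer of 2080 passed at random positions.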

Results

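Binding of the Rotund-eGFP fusion was measured in whole pupae, in 2 biological replicates of 1 group. Rotund is a C2H2 zinc finger protein known for its part in patterning the legs, antennae and wings. The thresholded set over both replicates held 3777 peaks with a median width of 296 bp, 3774 of them on the main arms, and covered 1045 kb or 0.781% of the arms. The authors' signal value had a median of 79.7 (quartiles 60.1 and 119) and a maximum of 1133. The conservative set held 3615 peaks, and the replicates' own sets held 2377 and 2114. Replicate values below are signals from each replicate's own ranked list.

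At rn itself (FBgn0267337, 3R:7272617-7309629, minus strand), 5 peaks were called. The strongest lay at the promoter, at 3R:7309683-7309978, with its summit 202 bp upstream of the transcript start. Its signal was 90.8, rank 1521 of the set, and 48.8 and 44.8 in the replicates. A coding exon held a peak at 3R:7307940-7308235 with a signal of 56.9, and the other 3 lay in introns with signals of 45.9, 50.3 and 46.0. A stronger peak stood just beyond the window used for the gene, at 3R:7310669-7310964, with a signal of 106. The count for rn was 2 to 3 peaks in the single replicates' sets and 1 at an IDR of 0.001.

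**Figure D1:**
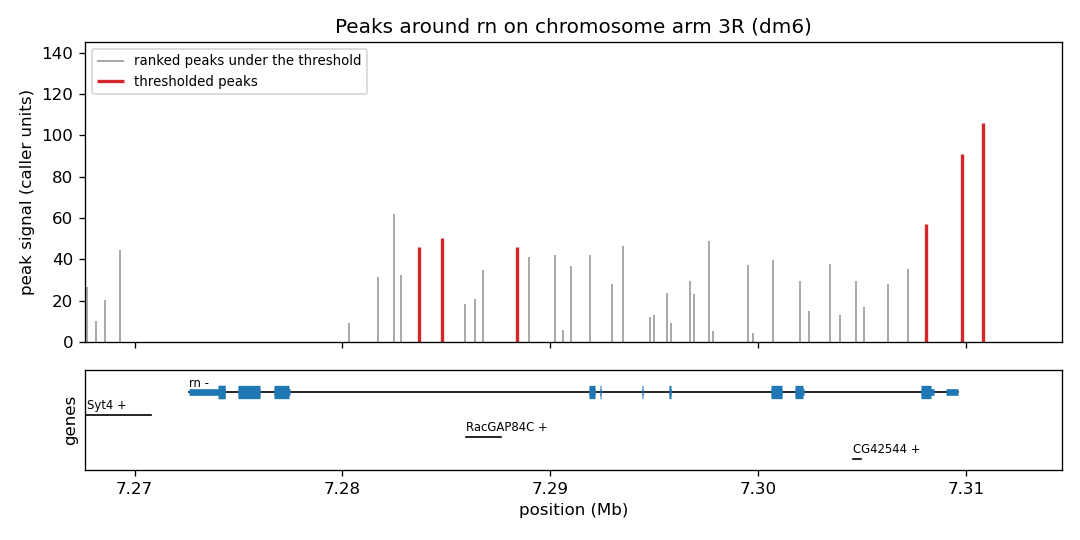
Map of rn on arm 3R (dm6). The upper panel has the signal of each peak in caller units against position in Mb, with the thresholded peaks in red and ranked peaks under the threshold in grey. The lower panel has rn with its exons in blue (coding parts thick) and its neighbours, each with its strand. The tallest peaks, with signals of 90.8 and 106, stand at and upstream of the rn start on the right.

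The paralogs bab1 and bab2, transcription factor genes that act with rn in tarsal leg patterning, both had peaks. At bab1 there were 3 intronic peaks, the strongest at 3L:1089300-1089595 with a signal of 122 (59.9 and 62.2 in the replicates). At bab2 there was an intronic peak with a signal of 61.9 and an intergenic peak 991 bp upstream of the start, at 3L:1178119-1178414, with a signal of 78.5 (47.7 and 32.4). The related zinc finger gene sqz had 3 called peaks, the strongest at its promoter (3R:19164042-19164337, signal 55.9). Another, at 3R:19164274-19164569 with a signal of 21.1, overlaps it, so the 3 need not be separate sites. The bab2 peaks were absent from both single-replicate sets, and the sqz peaks were absent from that of replicate 2 and at an IDR of 0.001. The pigment gene y had 1 weak promoter peak (X:356392-356687, signal 43.3) that no single-replicate set held, and w had none (1 in the conservative set). The mean signal of ranked peaks within 20 kb of rn lay at the 91.8th percentile of random genes (95% Wilson interval 89.9 to 93.4), against 62.6 for w and 67.2 for y. In the ranked lists of replicates 1 and 2 the percentile was 81.5 and 80.3 for rn, 85.5 and 79.4 for w and 91.6 and 69.8 for y.

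The strongest peaks sat mostly at promoters. The highest signal, 1133, was at the start of the UDP-galactose transporter gene Ugalt (X:2703751-2704016; 586 and 557 in the replicates). CG14100 followed at 3L:19590492-19590742 with 1106. The next included mRpL41 (2R:15217629-15217877, 980) and mRpS10 (3R:15229410-15229667, 826), which encode mitochondrial ribosomal proteins, the mitochondrial exoribonuclease gene PNPase (3R:31404549-31404781, 831) and the complex I assembly factor gene CIA30 (3R:29736731-29736977, 806). Tcs5 (3L:5139380-5139617, 856) and CG8320 (2R:15992378-15992616, 761) also had promoter peaks. The summits at mRpL41, mRpS10, CIA30, Tcs5 and CG8320 lay within 500 bp of the start of another gene as well (lncRNA:CR44463, Art3, CG7601, CHMP2B and Pex11ab). The other 2 of the top 10 lay in introns of CG11050 (2L:6612580-6612833, 868) and of the transcription factor gene Adf1 (2R:6662936-6663186, 726). All 10 were called with signals of 353 or more in each replicate. The ranked list held 2 stronger peaks than the tenth of these that the thresholded set lacks, in ush and Lk6.

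Across the set, promoters held 1453 summits, or 38.5% (95% Wilson interval 37.0 to 40.1), against 13.4% after circular shifts, a 2.87-fold excess. Introns held the largest share, 42.8%, above the shifted 39.4%. Intergenic sequence held 15.2% against 27.6%, other exons 2.46% against 5.78% and coding exons 1.06% against 13.8%. All 5 classes differed from the shifted mean. The two-sided p was 0.002 for introns and 0.001, the smallest that 1000 shifts can give, for the others, and the adjusted p was at most 0.002. Promoter peaks had a median signal of 85.0 and other peaks 77.0, a difference of 8.01 (permutation p = 3e-05, 1453 against 2321 peaks). The promoter share was 32.6% below the lower quartile of signal and 47.7% above the upper quartile, and 64 of the 100 strongest peaks were at promoters.

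**Figure D2:**
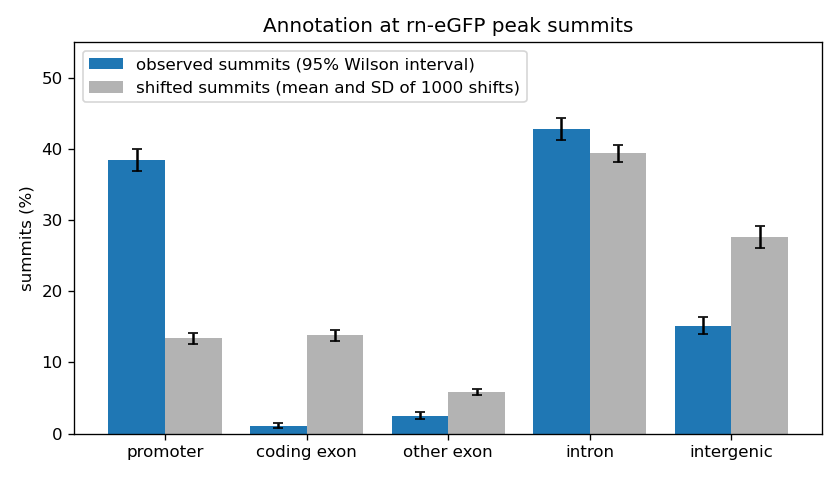
Share of the 3774 summits in each annotation class in percent (blue, with the 95% Wilson interval) beside the share after circular shifts (grey, mean and SD of 1000 shifts). Promoters stand at 38.5% against 13.4%, and coding exons at 1.06% against 13.8%.

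A peak was given to 2554 of 13945 protein-coding genes (18.3%), and 1693 genes had a peak within 500 bp of a start. Of the 22 gene lists, 4 held more genes with a peak than length-matched lists and 3 held fewer, at an adjusted p under 0.05 in the permutation test. Genes of EGFR signalling were among the first group, with 13 of 16 carrying a peak against 6.30 for matched lists (adjusted permutation p = 0.00554). They included the receptor gene Egfr (4 peaks, strongest 324 in an intron, 2R:21524201-21524371), the cell adhesion gene ed (7 peaks, strongest 284), the pathway inhibitor sty (2 peaks, 268) and the ETS repressor gene aop (8 peaks, 236). The transcription factor gene pnt had 6 peaks and the secreted inhibitor aos had 3. In the sets of replicates 1 and 2 alone ed had 2 and 1 peaks, aop 3 and 5, and pnt 3 in each. Of 70 named genes followed across the sets, 30 and 28 had counts lower by over 1.5 times there.

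Genes of the Hippo pathway and growth had peaks in 9 of 11 cases against 3.62 (adjusted permutation p = 0.00554). Their strongest peaks were in introns of the growth regulator Myc (X:3381827-3381995, signal 308), of the upstream regulators kibra (286) and ex (188), and of the apical polarity gene crb (162). The kinase gene wts had 5 peaks and the coactivator gene yki had 1. In the Notch pathway 11 of 23 genes had a peak against 4.63 (adjusted permutation p = 0.00609), led by the ubiquitin ligase gene neur (3R:9031925-9032117, 370), numb (159), the receptor gene N (156) and fng (150). The fold was 2.37 over matched lists. In the sets of replicates 1 and 2 alone it was 2.04 and 2.19 with 7 genes each, and the list did not pass (adjusted permutation p = 0.146 and 0.119), nor did it at an IDR of 0.001 (1.87-fold, 6 genes). None of the 3 signalling lists passed when only promoter summits were counted, with folds of 2.03 (EGFR), 2.24 (Hippo) and 1.93 (Notch) over matched lists and 6, 4 and 5 genes.

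Ribosomal protein genes formed the largest of the 4 lists with more peaks than expected. Of 92 such genes 33 had a peak against 9.57 for matched lists (adjusted permutation p = 0.00022, from the smallest p the permutations can give), 32 of them at a promoter. The strongest were RpS19b (signal 244, 904 bp upstream of its start, inside an intron of another gene), RpS27 (3R:25247461-25247585, 172), RpL34b (163) and RpL7 (161). In the sets of replicates 1 and 2 alone 17 and 20 of them had a peak (2.58-fold and 3.15-fold of matched lists, against 3.45-fold in the set over both). This list passed under each alternative run.

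Genes for cuticle proteins and chemoreceptors were nearly free of peaks in their bodies and the 1000 bp upstream. Only Cpr65Au among 115 cuticle protein genes had a peak, against 11.7 for matched lists (adjusted permutation p = 0.000587). Only Ir85a among 120 gustatory and ionotropic receptor genes had a peak, against 16.2 (adjusted permutation p = 0.00022), and only Or88a among 61 odorant receptor genes, against 7.36 (adjusted permutation p = 0.0216). The signals at Ir85a and Or88a were 48.1 and 66.5. None of these 3 genes had a peak in either single-replicate set, nor had Cpr65Au in the conservative set, where 2 other cuticle protein genes did. The odorant receptor list did not pass at an IDR of 0.001, where no member kept a peak, so its depletion was not weaker there. It also did not pass with 5000 bp upstream counted. Both chemoreceptor lists did not pass when peaks went to the nearest start (4 and 7 genes).

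The remaining lists did not pass. Ecdysone response genes came closest, with 15 of 22 carrying a peak against 9.61 (adjusted permutation p = 0.0681), among them ImpL2 (3L:4228287-4228476, 460), the nuclear receptor gene Hr4 with 11 peaks, ftz-f1 with 7, Eip75B with 6 and EcR with 2. This list passed with the nearest start (adjusted permutation p = 0.0189). Leg and antenna patterning genes had a peak in 9 of 26 cases against 9.76 (adjusted permutation p = 0.963), with 8 peaks at hth, 1 at Dll and 1 at dac. It had 3 and 4 genes in the sets of replicates 1 and 2 alone (0.40-fold and 0.57-fold of matched lists), and 14 with the nearest start (1.66-fold, adjusted permutation p = 0.0848). Wing patterning genes had 13 of 26 against 11.4 (adjusted permutation p = 0.785), led by dpp (304) and bs (214). Planar polarity and joint genes had 7 of 15 against 5.83 (adjusted permutation p = 0.811), led by bowl (286) and ds (285). Olfactory neuron factors had 6 of 13 against 4.34 (adjusted permutation p = 0.627), led by zf30C (159) and Eip93F (147). Proneural and sensory organ genes had 2 of 13 against 2.95 (adjusted permutation p = 0.855), emc and ct. Axon guidance genes had 11 of 29 against 13.5 (adjusted permutation p = 0.627), led by PlexA (216) and Sema1a (195). Hox genes had 2 of 8 against 3.87 (adjusted permutation p = 0.517), Antp and Abd-B, and none in the set of replicate 1 alone or at an IDR of 0.001.

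Cell type markers were read as gene lists only, since whole animals mix all tissues. Neuron markers had a peak in 3 of 14 cases against 6.08 (adjusted permutation p = 0.295), with elav (159) and Rbp9 (124) strongest. Glia markers had 3 of 10 against 2.62 (adjusted permutation p = 1), led by moody (218) and loco (155). Muscle markers had 5 of 20 against 6.88 (adjusted permutation p = 0.643), led by kirre (17 peaks in 394 kb, strongest 223) and sls (153). No marker of fat body (10 genes, 1.65 for matched lists, adjusted permutation p = 0.515), hemocytes (9 genes, 3, adjusted permutation p = 0.11), trachea (7 genes, 2.35, adjusted permutation p = 0.222) or germline (13 genes, 2.03, adjusted permutation p = 0.378) had a peak, and these lists did not pass the permutation test.

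**Figure D3:**
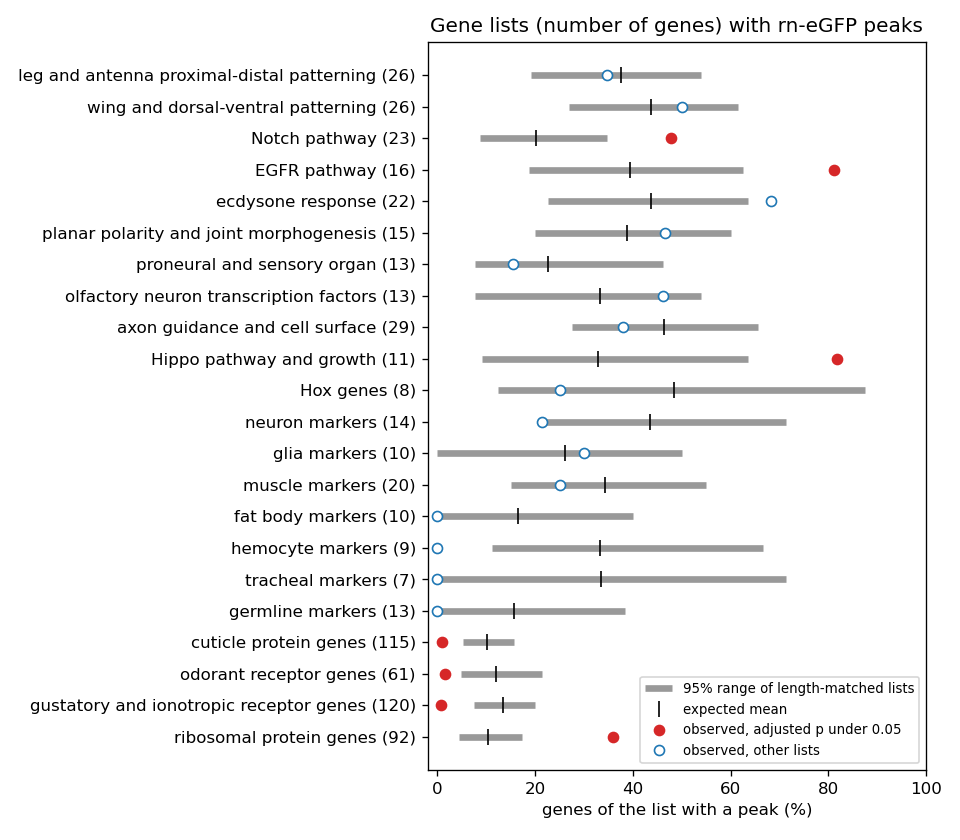
Genes with a peak in each of the 22 lists, in percent of the list (the number of genes stands in brackets). Grey bars give the 95% range and black ticks the mean of length-matched random lists, red points the lists with an adjusted p under 0.05 and open points the others. EGFR pathway genes stand at 81.2% and ribosomal protein genes at 35.9%, above their ranges, and cuticle protein genes at 0.87%, below theirs.

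Summit sequence was rich in A and T. G and C made up 34.3% ± 12.1 (SD, 3774 summits) of the 51 bp at the summit and 44.5% ± 8.30 at a distance of 200 bp. Of 17 fixed motifs, 3 were more frequent within 50 bp of summits than in flanks. A run of A (AAAAAAA) was found at 17.7% of summits and 10% of flanks (adjusted exact p = 1.39e-21), the homeodomain core TAATTA at 8.90% and 6.12% (adjusted exact p = 2.44e-05), though its log2 ratio of 0.53 was below the median of 0.94 for 13 reorderings of its bases, and the DNA replication-related element TATCGATA at 0.768% and 0.318% (adjusted exact p = 0.0179). The call for TATCGATA did not hold within 25 bp (adjusted exact p = 0.107) or in replicates 1 and 2 alone (log2 ratio 0.25 and 0.96, adjusted exact p = 0.884 and 0.234), and its ratio was -0.44 at an IDR of 0.001. Another 9 were less frequent, among them CACACA (6.89% against 10.9%, adjusted exact p = 5.38e-09), the Pho core GCCAT (13.2% against 17.8%, adjusted exact p = 3.76e-07) and the ETS core CMGGAA (4.90% against 7.10%, adjusted exact p = 0.000234). The Su(H)-like motif TGGGAA (4.74% against 5.72%) did not pass (adjusted exact p = 0.0813).

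Of 2080 6-mers, 386 were more and 855 less frequent at summits at an adjusted p under 0.05. The 10 with the lowest p were TTAAAA (30.4% of summits against 14.8% of flanks, exact p = 2.63e-57), ATTTAA, AAATAT, AAAATA, ATTTTA, AATATA, AAAAAT, AAATAA, TTTAAA and TAAATA, made of A and T alone. With base composition held, 126 6-mers had a higher summit to flank ratio than the median 6-mer of equal G and C count. None of the 10 above was among the first 10 of that comparison. Against the median of reorderings of their own bases, the log2 ratio differed by -0.41 for TAATTA, -0.37 for CACACA, 0.027 for GCCAT, -0.020 for CMGGAA and 0.51 for TATCGATA, with too few reorderings for a single motif to pass a test.

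**Figure D4:**
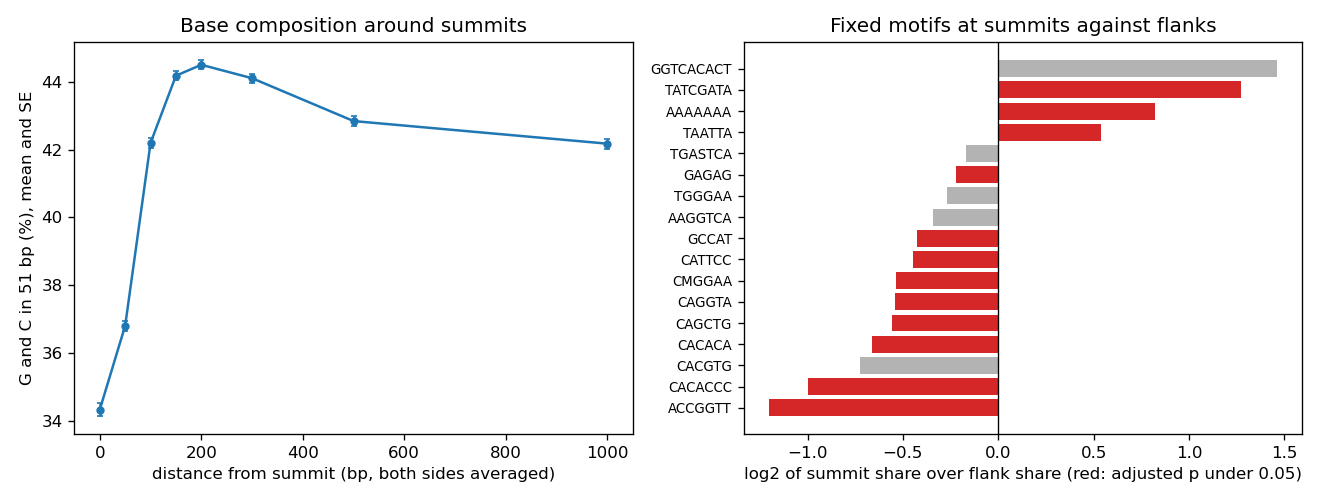
Left, mean G and C content in percent of 51 bp windows (error bars SE, 3774 summits) against distance from the summit in bp, which rises from 34.3% at the summit to 44.5% at 200 bp. Right, log2 of the share of summits over the share of flanks with each fixed motif, red where the adjusted p was under 0.05, with TATCGATA, AAAAAAA and TAATTA the red bars above 0.

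Most peaks called in a single replicate were also called in the other, and the strong ones nearly always. Of 2375 replicate 1 peaks on the arms 1575 (66.3%, 95% Wilson interval 64.4 to 68.2) met a replicate 2 peak, against 0.833% after circular shifts. Of 2112 replicate 2 peaks 1569 (74.3%, interval 72.4 to 76.1) met a replicate 1 peak, against 0.93%. The one-sided p was 0.001 in both directions, the smallest that 1000 shifts can give. Above the upper quartile of signal 98.3% of replicate 1 and 99.2% of replicate 2 peaks were shared, and below the lower quartile 31.3% and 42.6%. Over the 1575 shared peaks the signals correlated with Pearson's r = 0.922 and Spearman's rho = 0.789 (permutation p = 1e-05 for both, the smallest possible), and r was 0.915 without the 2 peaks farthest from the median. The median distance of summits was 16 bp. Of the set over both replicates, 1568 peaks (41.5%) had a partner in both single-replicate sets and 1029 (27.2%) in neither.

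**Figure D5:**
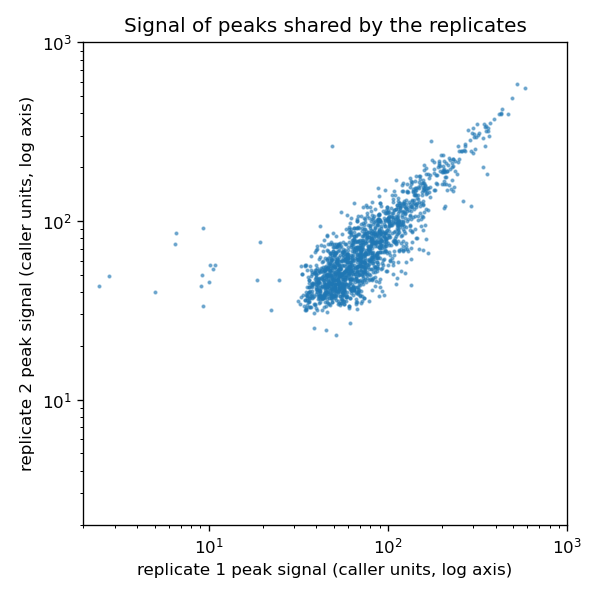
Signal of the 1575 shared peaks in replicate 2 against replicate 1, in the caller units of each list on log axes. The signals rise together, with Spearman's rho = 0.789.

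The X chromosome held 686 peaks, 29.1 per Mb, against 28.0 per Mb on the autosomes. The ratio of 1.04 (95% interval 0.957 to 1.13) did not differ from 1 (exact binomial p = 0.336). In the set of replicate 1 alone the ratio was 1.12 (exact p = 0.0355), and it was 1.15 at an IDR of 0.001 (exact p = 0.00926), while replicate 2 alone gave 1.04. The arms 2L, 2R, 3L and 3R had 28.5, 27.3, 29.9 and 27.6 peaks per Mb. Chromosome 4 had 1 peak, at the promoter of PlexA (4:1027211-1027343, signal 216).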

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

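The tests of transgene copies, of transcribed promoters, of RNA polymerase III genes and of base composition in peaks under the threshold were set before their results were seen. The tests of paired genes, of peaks outside promoters and of A runs, and the use of the highest percentile over the planned windows and lists, were chosen after the result was seen.

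The ranked list held 87 peaks at or above the threshold score that the thresholded set lacked, which is signal in data outside the main measurement. Of these, 46 lay on 3R and 26 on 2L, and 51 lay within 10 kb of another such peak. Their median signal was 70.6, and 22 exceeded the upper quartile of the thresholded set (119). The strongest, at 2L:480952-481229 in ush, had a signal of 917, followed by 734 in Lk6 (3R:11760943-11761153) and 608 in larp (3R:28326473-28326699). The first would rank 4 in the thresholded set. The deposited notes list for the thresholded sets a further parent file that the ranked lists lack and do not state its role. Whether it removed these peaks was not tested.

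Promoters of ribosomal protein genes carried peaks in 32 of 92 cases, and capture of strongly transcribed promoters without regard to Rotund would make these peaks stronger than others. Their median was 69.8 against 85.2 (difference -15.4, 34 against 1419 peaks, permutation p = 0.138), which leaves this open, as do tRNA genes, with a summit within 500 bp at 12 of 290 against 8.06 after shifts (p = 0.329). Of 1351 promoter summits within 500 bp of a protein-coding start, 32.3% lay near starts on both strands, against 25.3% at the same offsets from random starts (Fisher p = 6.45e-05). That baseline was 14.4% when the drawn start had to be the nearest to the position, and 14.6% when drawn over genes in this way. Starts on both strands were counted whether or not they point away from each other. A preference for promoters with starts on both strands stays open for ribosomal protein genes. Of their 34 promoter peaks 52.9% lay near such starts, against 33.3% at the 60 ribosomal protein genes without a promoter peak (Fisher p = 0.0811). No control library was analysed here, and no biological explanation was tested against a second group.

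G and C content changed from flank to summit by -7.89 percentage points (95% interval -8.32 to -7.46). A composition bias of any called peak predicts the same fall in the 122328 ranked peaks under the threshold, which instead had a rise of 4.15 (4.09 to 4.22). This argues only against a bias shared by strong and weak peaks alike. With no control library analysed, a bias limited to strong peaks could not be tested. Promoter sequence alone is also argued against, since peaks outside promoters had a change of -6.84 (-7.35 to -6.32) against -9.56 at promoters. The ratio of summit to flank share of AAAAAAA lay at percentile 22.2 of the 64 7-mers made of A and T. Its log2 ratio was 0.81, against 1.43 for the highest, TTTAAAA. Among these 7-mers AAAAAAA had the highest share of summits, 17.7%, and also the highest share of flanks. These ratios argue against a run of A as the preferred site among the 7-mers of A and T. They do not exclude that runs of A contribute. A broader preference for sequence rich in A and T may account for the pattern, and open chromatin outside promoters, which was not measured, stays possible.

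Extra DNA copies of rn and of a marker gene on the transgene could raise signal around both. Among random genes the percentile of rn was 91.8 within 20 kb and at most 92.8 (upper 95% limit 94.3) over 3 windows and 3 ranked lists, under the 95th percentile set beforehand for this explanation. That limit covers the draw of random genes and not the spread of signal at rn. In replicates 1 and 2 the percentile of rn within 20 kb was 81.5 and 80.3. That of w was unsteady, at 62.6 (59.5 to 65.5) within 20 kb, 85.5 and 79.4 there in replicates 1 and 2, 93.6 within 5 kb (93.6 and 95.4 in the replicates) and 38.5 within 50 kb (77.6 and 78.7). The gene w lies inside kirre, whose strongest peak (X:2786736-2786833, signal 223) is within 20 kb of it. The percentile of w therefore also reflects peaks of kirre. The bound at the 95th percentile cannot exclude copies, since their number is not known and no control library was analysed here. Extra copies stay open. No biological explanation was tested.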

How the results depend on the processing

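Of the values of the main results under alternatives, without the IDR of 0.01 that removed no peak, 76 kept their direction and side of the threshold or, for counts, stayed within 1.5 times, 11 moved further and 2 gained a call. The replicate overlaps and correlation, the promoter share and the stronger signal of promoter peaks did so under every alternative run, the reciprocal overlap with fewer shifts (p = 0.0099, the smallest possible). With the IDR at most 0.001, added after the data were examined, 2110 peaks remained, the X to autosome ratio was 1.15 and the log2 ratio of TATCGATA turned to -0.44. With a replicate left out, the number of peaks ranged from 2112 to 2375 and the X ratio from 1.04 to 1.12. Counting promoter summits only left 1693 genes with a peak and 1 enriched list, ribosomal protein genes. The nearest start left 1 list with fewer peaks, cuticle protein genes. With a Fisher test without length matching 9 lists were enriched, and 8 with a permutation test without it, added later. Axon guidance genes turned from fewer to more than expected in both (2.07-fold). With base composition held, also added later, 126 6-mers led. Fixed motifs were set against reorderings of their bases, but these were at most 196, too few for a single motif to pass, so no result is drawn. The log2 ratio of GAGAG was -0.22 in the main windows. Within 100 bp of the summit it was 0.00905, a change of sign but almost no difference from the flank. The percentile of signal around rn was 81.5 and 80.3 in the ranked lists of replicates 1 and 2. The cause of these shifts was not tested further. Among single lists, motifs and genes, 501 values were as before, 28 lost and 16 gained their call, 87 moved and 4 turned. Read depth is unknown, so its effect on weak peaks could not be measured.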

Other observations

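The families and genes below, and their tests, were chosen after the data were examined.

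Genes for the basal transcription machinery were a further group with peaks. Of 49 genes for Mediator subunits, TATA-binding protein associated factors and general transcription factors, 15 had a peak against 6.64 for length-matched lists (adjusted p = 0.0283 over 14 families, permutation), each at a promoter. The strongest were MED30 (169), MED27 (159), MED31 (121) and Taf5 (116). All these families were taken by gene symbol, here those starting with MED, Taf or TfII, so they need not be complete. They were tested in the set over both replicates only, and not in the single replicates' sets. RNA polymerase subunit genes had 8 of 30 against 3.62 (adjusted permutation p = 0.181) and cytochrome P450 genes 5 of 85 against 12.7 (adjusted permutation p = 0.107). Proteasome genes had 5 of 48 against 5.18, nuclear genes for complex I had 6 of 40 against 4.58 and translation initiation factor genes had 9 of 44 against 7.86, with an adjusted p of at least 0.731 in the families not given one. The genes with most peaks were sbb (22 in 79.1 kb), kirre (17 in 394 kb) and Snoo (14 in 93.0 kb). CG1677, psq and shn followed with 12 each (in 125, 59.4 and 58.3 kb). These counts are not adjusted for gene length. In the sets of replicates 1 and 2 alone sbb had 14 and 13, kirre 12 and 12, and Snoo 9 and 9.

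Nuclear genes for the mitochondrial ribosome were examined because mRpL41 and mRpS10 were among the strongest peaks. Without these 2, 11 of 71 such genes had a peak against 6.03 for length-matched lists (95% range 2 to 11), 9 of them at a promoter. They did not pass (permutation p = 0.0676, adjusted p = 0.237 over the 14 families), so whether they are targets as a group stays open. The strongest of the rest were mRpS23 (664) and mRpL23 (637).

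With base composition held, 6 of the 10 leading 6-mers held the core CAGTG or its reverse complement CACTG. The log2 ratio here is of peaks with the 6-mer only at the summit to peaks with it only in the flank. It was set against the median of 6-mers of equal G and C count, and the composition of the windows was not held. CAGTGC was at 6.94% of summits and 4.93% of flanks (log2 ratio 1.19 above that median, adjusted exact p = 2.84e-14). CACTGA was at 7.18% and 4.56% (1.02 above, adjusted exact p = 3.31e-10). The third, GTGCAC, lacks it.

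Chromosome 4 had 1 thresholded peak where its length would give 38.0 (exact binomial p = 2.53e-15), and 54 ranked peaks where its length would give 1271. In the set, 73 peaks had a signal under 20, down to 2.30. A weak peak can overlap a stronger one, as at sqz, so peak counts need not be counts of separate sites.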
